A study of Pimephales promelas with 12 samples.

How the data were processed

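RNA of 12 whole ovaries, 6 from control fish and 6 from fish exposed to a nominal 50 µg haloperidol/L for 96 h in flowing water, was measured on 2-colour Agilent arrays, with the ovary in Cy5 and a common reference pool in Cy3 on every array. Groups were taken from the source labels, and replicate numbers only name the fish. Per the labels' protocols, 3 tanks per treatment gave 2 ovaries each. No paired analysis was possible because the labels do not tie fish of the groups to each other.

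The deposited scanner files hold spot intensities of both channels with no normalization, written by Agilent Feature Extraction 9.5 per the submitters' processing notes. The deposited log10 ratios of Cy5 over Cy3 were background-subtracted and dye-normalized by that software per the file headers. The series matrix table deposited by the authors holds the same log10 ratios: all 44407 spots of each array matched within rounding to 3 significant digits, and each array's median value was 0. They were not centred on genes, and between 35.3% and 48.1% of the spots of an array have a log10 ratio of exactly 0 in the deposited files.

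From the intensities, the mean signal of each spot was corrected with its median local background by normexp with an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess, with control spots at weight 0. No scaling between arrays was applied. Control spots and spots flagged as non-uniform or population outliers in either channel were left out; 4.26% to 11.0% of spots per array were so flagged. The spots of a probe were averaged. A probe was kept if it was well above background in Cy5 on at least 6 of the 12 arrays in at least 1 spot, which kept 9980 of 21495 probes (46.4%). Of these, 9848 had enough values for a fit. The median Cy5 signal of an array ranged from 270.2 to 526 scanner units against a median local background of 116 to 150.

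Groups were compared with limma 3.58.1 in R 4.3.3, lmFit and eBayes on the log2 ratios, haloperidol minus control, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The slide of each array was taken from the scanner files and tested as a batch. A moderated F test of the slide called 0 of 9528 probes, with 608 at an unadjusted p under 0.05 where 476 are expected. The script was tested on simulated data with the spread of the real probes: of 9848 probes, 200 were changed by known amounts, and 75% of the 2-fold and 88% of the 4-fold changes were recovered, with 12 of 175 calls among unchanged probes. With known changes added to the real values instead, 1 of 164 calls was an unchanged probe. With no change simulated, 0 probes were called and 496 had an unadjusted p under 0.05.

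The probe names of the deposited files are mostly clone, contig or sequence accession names: 6937 of 21495 probes carry an accession, of which 0 were found in the table of 64593 RefSeq genes of the assembly fPimPro1.hap1.1, and 14525 carry an EST, contig or clone name. In the files, 33 probes have a gene name in plain words, and only these are named. Named genes were to be the 10 largest rises and 10 largest falls among called probes with a gene name and the same direction in at least 5 of 6 treated fish, filled to 10 with the smallest unadjusted p, up to 4 members of each fixed list, and a fixed set of steroid, gonadotropin, dopamine, vitellogenin and egg envelope genes. With 0 calls, this rule took all 9 named genes that were tested, and 20 gene lists were matched by symbol or phrase. Lists were to be tested with camera at a preset correlation of 0.01 where they had 3 or more tested genes, and 0 lists did. The design, the lists and most alternatives were fixed before the data were examined.

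Alternatives were no background subtraction, Agilent's processed signals, median centring, Aquantile or scale normalization between arrays, Cy5 alone with quantile normalization, the series matrix values, no brightness filter, a filter on all 12 arrays, eBayes with trend and robust settings, array weights, the slide as a block, each fish left out, and an adjusted p under 0.1. Chosen after seeing the data were keeping flagged spots, a filter on at least 3 of the 12 arrays, leaving out the 3 fish with high alpha amylase, and leaving out the 2 arrays with the least alike duplicate spots.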

Results

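Ovaries of 12 female fathead minnows (Pimephales promelas), a small cyprinid used in toxicity testing, were profiled after 96 h in control water or in water with a nominal 50 µg haloperidol/L. Haloperidol is an antipsychotic drug that blocks dopamine receptors. Each group had 6 fish, and each ovary (Cy5) was hybridised against 1 common reference pool (Cy3) on an array of 21495 probes with 2 spots each. The pool came from control fish and held gonad, liver and brain RNA per the labels. Between 8552 and 11370 probes per array were well above background in Cy5. Their number was 9931 ± 794 (SD, n = 6) in control and 9914 ± 939 (SD, n = 6) in haloperidol fish. The number of arrays limits the precision of every value given here.

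The comparison of the groups asks which ovarian transcripts differ after haloperidol exposure. No probe passed the test: limma called 0 of 9848 probes at an adjusted p under 0.05, 0 higher and 0 lower, and the smallest adjusted p was 0.99999. At an unadjusted p under 0.05 there were 285 probes, 125 higher and 160 lower, where 492 are expected by chance. At an unadjusted p under 0.001 there were 2, where 10 are expected. The p-values were spread as in the plot of their distribution, with the fewest probes in the lowest bin.

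**Figure D1:**
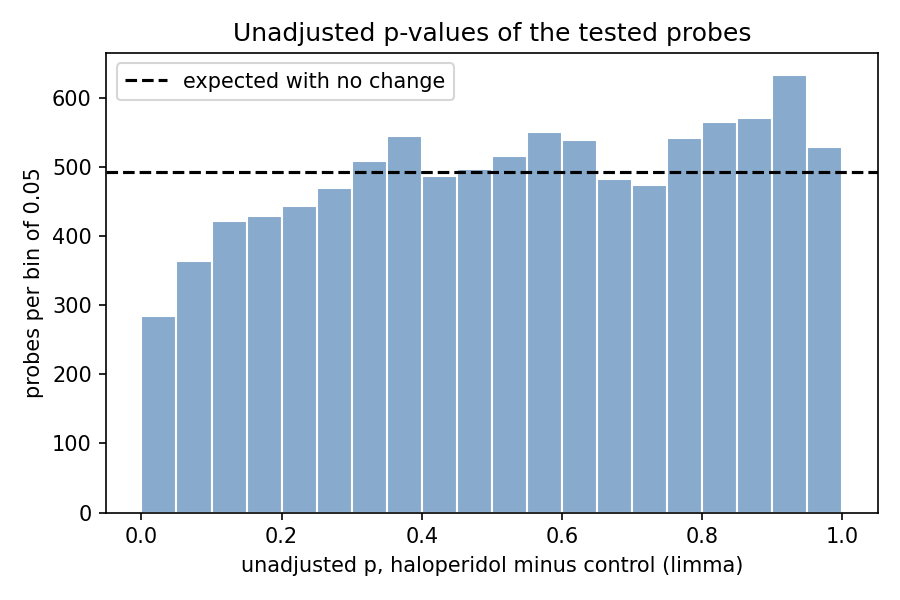
Unadjusted limma p-values (x axis, bins of 0.05) of the 9848 tested probes, haloperidol minus control, with the number of probes per bin on the y axis and the number expected with no change as a dashed line. The lowest bin holds 285 probes and the bin from 0.9 to 0.95 holds 633.

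Zona pellucida glycoprotein 3, a protein of the egg envelope, was well above background in all 12 ovaries, at a log2 ratio to the reference of -0.41 ± 0.21 (SD, n = 6) in control and -0.43 ± 0.46 (SD, n = 6) in haloperidol fish. Its difference of -0.02 had a standard error of 0.20, and its 95% interval ran from 0.74-fold to 1.33-fold. Cyclin B1, the regulatory partner of the kinase that drives oocyte maturation, was well above background in all 12 ovaries and had a value in 5 fish of each group. Its log2 ratio was 0.13 ± 0.18 (SD, n = 5) in control and -0.06 ± 0.24 (SD, n = 5) in haloperidol fish. The difference of -0.19 had a standard error of 0.14 and an interval from 0.71-fold to 1.09-fold, and 4 of the 5 measured haloperidol fish lay below the control mean. ACTRIIB, a receptor for activins, was well above background in 9 ovaries and differed by -0.05 with a standard error of 0.13, an interval from 0.79-fold to 1.17-fold. The direction of the differences of zona pellucida glycoprotein 3 and ACTRIIB turned when single fish were left out.

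Complement C3S, a complement component made mainly in liver, had a log2 ratio of -1.27 ± 0.60 (SD, n = 6) in control and -0.21 ± 1.78 (SD, n = 6) in haloperidol fish. Its difference of 1.06, with a standard error of 0.68 and an interval from 0.75-fold to 5.82-fold, did not pass the test, although 5 of 6 haloperidol fish lay above the control mean. In haloperidol 3 alone the log2 ratio reached 3.11, and without that fish the difference was 0.40. The gene was well above background in 3 of 6 control and 5 of 6 haloperidol ovaries. Pentraxin, an acute-phase protein, was measured in all 12 ovaries and differed by 0.02 with a standard error of 0.17, an interval from 0.79-fold to 1.31-fold; this direction too turned when single fish were left out. Adenosine deaminase, an enzyme of purine breakdown, differed by 0.33 with a standard error of 0.25, and the difference was 0.11 without haloperidol 2, whose log2 ratio was 1.16.

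Lamin B1, a protein of the nuclear lamina, had the smallest p-value of the named genes. Its log2 ratio was -0.61 ± 0.79 (SD, n = 6) in control and 0.03 ± 0.79 (SD, n = 6) in haloperidol fish, a difference of 0.64 with a standard error of 0.41. It was well above background in 3 of 6 control and 5 of 6 haloperidol ovaries, and the 3 lowest control values were not, so the size of the difference rests partly on values near background. The adjusted p of lamin B1 was 0.99999 over all probes and 0.49 over the named genes alone. Cytochrome b, a mitochondrially encoded subunit of the respiratory chain, differed by 0.28 with a standard error of 0.39. Its difference was -0.01 without control 1, -0.01 without haloperidol 3 and -0.30 without both. The duplicate spots on those arrays were the least alike, with correlations of 0.70 and 0.73 across probes.

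Alpha amylase, a starch-digesting enzyme made by the exocrine pancreas, had the widest spread of the named genes. Its log2 ratio was -3.26 ± 3.39 (SD, n = 6) in control and -4.37 ± 2.11 (SD, n = 6) in haloperidol fish. The difference of -1.11 had a standard error of 1.45 and an interval from 0.05-fold to 4.07-fold. It was -1.95 without haloperidol 5, -0.61 without control 5 and 0.06 without control 6. The gene was well above background in 6 control and 3 haloperidol ovaries. Another 6 probes without a gene name set the same 3 fish, control 5, control 6 and haloperidol 5, at least 2 log2 units above the others.

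**Figure D2:**
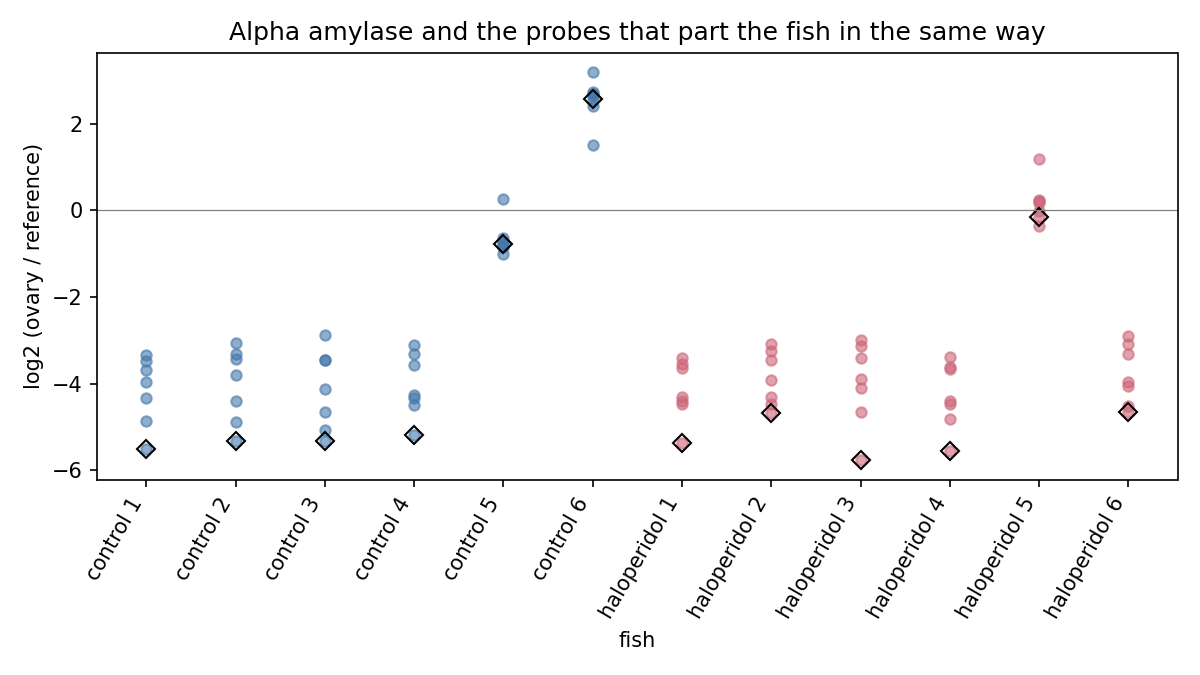
Log2 ratio of ovary (Cy5) to reference pool (Cy3) on the y axis for each of the 12 fish, with a point for each of the 7 probes that part the fish as alpha amylase does (control blue, haloperidol red) and an open diamond for alpha amylase. Control 6 lies highest, with alpha amylase at 2.57, haloperidol 5 at -0.16 and control 5 at -0.77.

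**Figure D3:**
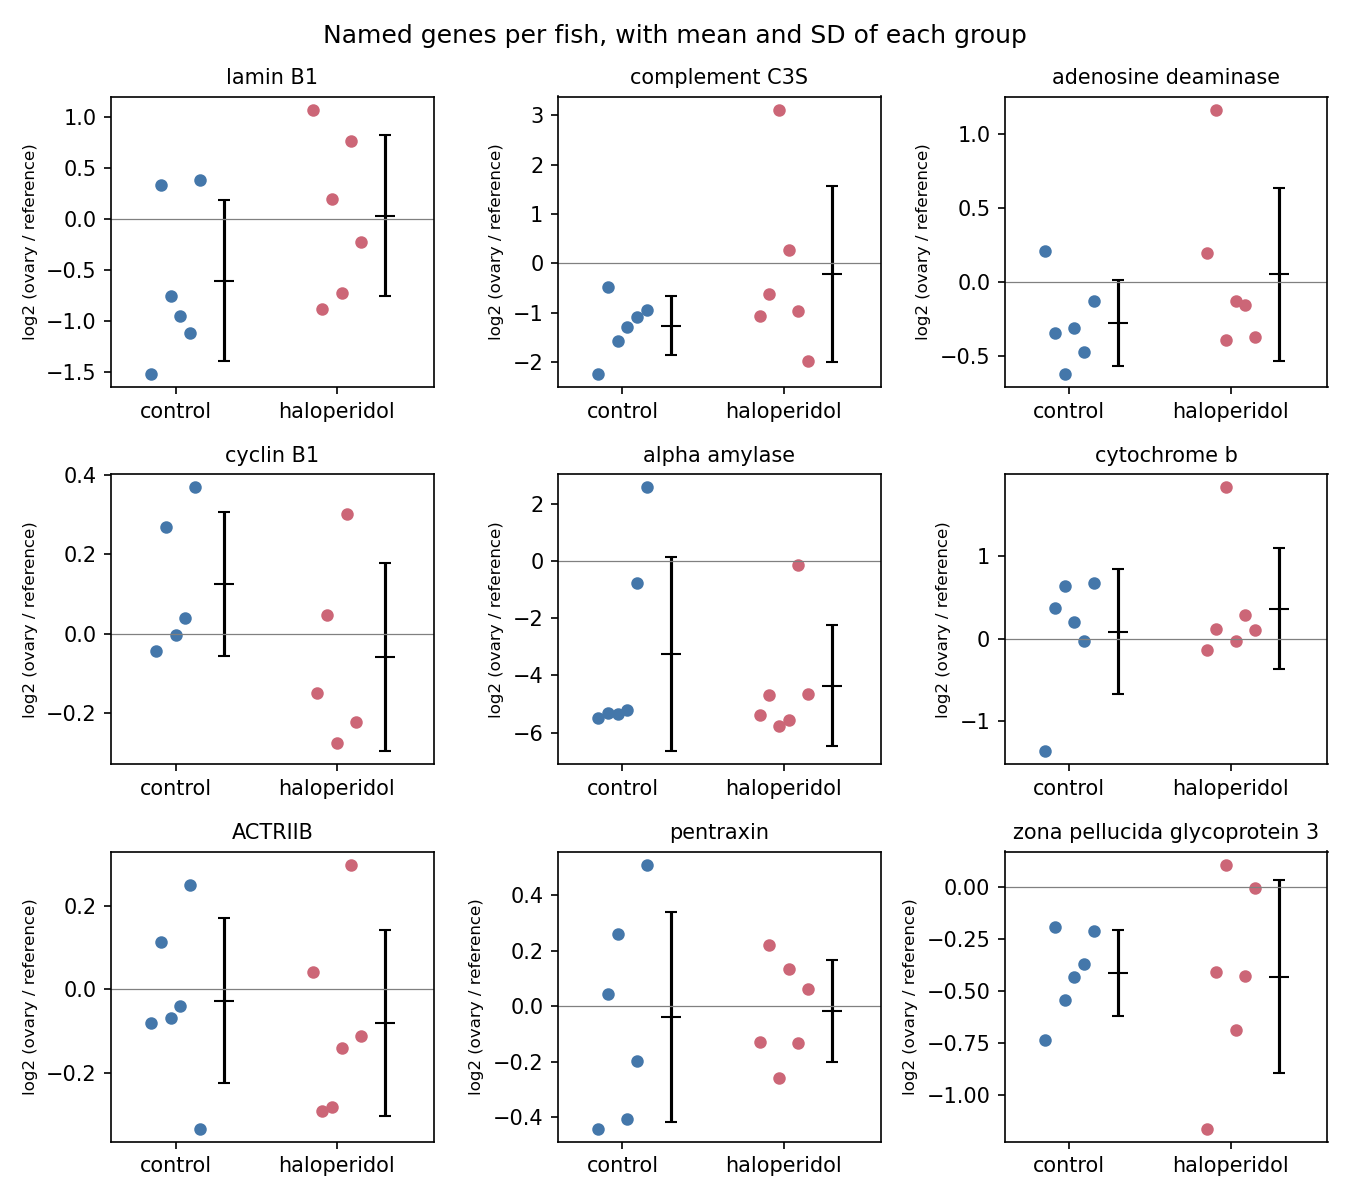
Log2 ratio of ovary (Cy5) to reference pool (Cy3) on the y axis for the 9 named genes that were tested, with a point per fish in control and haloperidol groups and the mean and SD of each group beside the points. The groups overlap in each of the 9 panels, and alpha amylase spans from -5.77 to 2.57.

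Of 33 probes with a gene name, 9 were tested, 5 of them higher and 4 lower on average, and 0 had an unadjusted p under 0.05 in limma. Estrogen receptor alpha, estrogen receptor beta, FSHR (the receptor of follicle-stimulating hormone), GnRH-III and inhibin beta b were not well above background in any ovary. These 5 probes were not well above background in the reference pool on any array either, so a silent gene cannot be told from a probe that does not detect it. Follistatin, which binds activin, was well above background in 1 control ovary, the inhibin probe in 2 ovaries, the taurine transporter in 1, and CD 18 type 2 and the myoblast determination protein in 5 each; in the pool these 5 were so on all 12 arrays. Of all probes, 12141 were well above background in Cy3 on all 12 arrays and 7752 were so in Cy5. The calls of these 5 named probes therefore do not by themselves show a lower level in the ovary. In all, 19 named probes were not well above background in any ovary, and 16 of these not in the pool on any array. Among the 16 were invariant chain like protein 1, a marker of antigen-presenting cells, and nebulin, a muscle protein.

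Of the 20 gene lists fixed for the tissue and the drug, 0 had the 3 tested genes that a test of the list needs. The oocyte and egg envelope list (zona pellucida glycoprotein 3), the oocyte maturation list (cyclin B1) and the liver and plasma protein markers (complement C3S) had 1 tested gene each. None of these 3 genes was called, over all probes or adjusted over the list alone. Lists were matched by symbol or fixed phrase. The list of gonadotropin, steroid and growth factor signalling matched 5 names with 0 tested, and missed the tested ACTRIIB, which it holds under another symbol. The leukocyte and skeletal muscle markers matched 1 name each with 0 tested. The other 14 lists matched no name: steroidogenesis, dopamine signalling, cholesterol synthesis, lysosome, vitellogenin uptake, ovulation, xenobiotic metabolism, stress response, apoptosis, red blood cell and stroma markers, ribosomal proteins, oxidative phosphorylation and the proteasome. Cytochrome b was not matched by the phrases of the oxidative phosphorylation list. Left out of the dopamine list was 1 probe labelled D2R with no gene name, whose meaning the files do not give. It was well above background in 1 control ovary, so it was not tested, and in the pool on all 12 arrays. Its log2 ratio of ovary to pool lay between -0.10 and 0.45 in the 12 fish, so these calls do not show a lower level in the ovary.

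Among unnamed probes, the smallest p-values of limma belonged to EA_Pp_64544, with a difference of -0.53 and a standard error of 0.11, and EA_Pp_68841, with a difference of -1.39 and a standard error of 0.33, each with 6 of 6 haloperidol fish below the control mean. In the other direction, EA_Pp_55019 differed by 1.15 with a standard error of 0.23 in 5 of 5 measured haloperidol fish. The limma adjusted p of these probes was 0.99999 each. Control fish with a value were not counted for them. With the slide as a block EA_Pp_55019 was at 1.08 and EA_Pp_64544 at -0.52. Both moved because some fish had no value, for EA_Pp_64544 among the controls.

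The median standard error of a difference was 0.17 on the log2 scale, and for 8652 of the 9848 probes (87.9%) the 95% interval lay within 2-fold either way. When known changes were added to 200 probes of the real data, limma recovered 72% of the 2-fold and 91% of the 4-fold changes. Calls of that size were thus possible with 6 fish per group when that many probes changed together. With fewer changed probes the adjusted threshold is stricter, and recovery in that case was not tested.

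The arrays lay on 3 slides, each with 2 control and 2 haloperidol fish. With the slide as a block, limma called 0 of 9756 probes, and 308 had an unadjusted p under 0.05. Within slides 1, 2 and 3, limma called 0 probes each, with 561, 432 and 372 probes at an unadjusted p under 0.05 where 430, 462 and 476 are expected. Slide 1 lay above expectation. At an unadjusted p under 0.001 there were 29, 25 and 15 where 9, 9 and 10 are expected, and the smallest limma adjusted p was 0.053, 0.18 and 0.14. The difference of complement C3S was 0.89, 2.04 and 0.26 within slides 1, 2 and 3, and 1 of the 9 named genes kept a single direction on all 3 slides. Lamin B1 differed by 2.06, 0.05 and -0.19 within slides 1, 2 and 3, adenosine deaminase by 0.23, 0.79 and -0.03, and cyclin B1 by 0.10, -0.22 and -0.45. The same differences were 0.43, 0.81 and -0.40 for cytochrome b, 2.65, -2.18 and -3.80 for alpha amylase, and 0.25, -0.47 and 0.06 for ACTRIIB. For pentraxin they were -0.04, 0.06 and 0.05, and for zona pellucida glycoprotein 3 -0.15, 0.13 and -0.03. With the slide as a block the difference of each of these genes stayed as given above. This was fixed by the design, since each slide held as many control as haloperidol values of each gene, so it tested nothing. Fish came from 3 tanks per treatment, 2 fish per tank, and the labels do not say which fish shared a tank, so p-values over fish may be too small.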

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

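The pattern of alpha amylase and the count of small p-values were noticed in the data, and the tests of the slide for alpha amylase, of the 2 least alike arrays, of pancreatic tissue, of splits with few small p-values and of probes that part the fish along the treatment were chosen only after the results were seen. The slide as a block was planned, but its use as a test of the count of small p-values, alone and over other splits, was chosen afterwards. Of 28 groups of 6 values looked at, 7 held a value far from the others, where chance gives about 1 in 20 for normally spread values. The 7 are not independent, since each lay in control 1, haloperidol 3 or haloperidol 5 and some are linked measures of the same array.

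Control 1 stood apart on technical measures. Its duplicate spots correlated at 0.70 across probes, against 0.85 to 0.91 in the other control arrays, with a standard deviation between spots of 0.36 against 0.13 to 0.15. The standard deviation of its log2 ratios across probes was 0.63, against 0.36 to 0.44. The duplicate spots of haloperidol 3 correlated at 0.73, against 0.87 to 0.93 in the other haloperidol arrays. Cytochrome b was lowest in control 1, at -1.36 against -0.03 to 0.68 in the other controls, and highest in haloperidol 3, at 1.83 against -0.14 to 0.29.

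Alpha amylase was at -0.16 in haloperidol 5, against -5.77 to -4.65 in the other haloperidol fish, and among controls at 2.57 in control 6 and -0.77 in control 5, against -5.50 to -5.19 in the other 4. The 2 spots of the 7 probes that part the fish in this way differed by a median of 0.12 log2 units over all 12 arrays. Most of these arrays held fish with low values, so this median cannot show whether the spots agreed in the 3 high fish. Faults of single spots therefore stay open. The slide is argued against, since the 3 fish lay on 3 slides. Pancreatic tissue left on the ovary may be a source, since exocrine pancreas is scattered along the viscera in cyprinid fish, but of a list of 9 pancreatic genes only 1, alpha amylase itself, has a named probe, so this cannot be told apart from expression in the ovary. High values occurred in both treatment groups, in 2 control fish and 1 haloperidol fish.

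The real grouping called 0 probes in limma, with 285 at an unadjusted p under 0.05. Of the 462 distinct splits of the 12 fish into 6 and 6, 100 were run, the real one included. All 100 call at least 0, so this count cannot test chance. The highest of the other 99 splits called 3, and 18 of them called at least 1.

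Fewer probes than expected had small p-values, 285 against 492. Chance cannot be excluded: 7 of the 100 splits, the real one included, gave as few as 285, and the other splits ran from 250 to 872. Differences between slides are argued against as the whole cause, since with the slide as a block the count was 308 where 488 are expected. A part is not excluded: an F test of the slide gave 608 where 476 are expected. The same holds for the 2 arrays with the least alike duplicate spots, without which it was 289 where 489 are expected. Differences between fish that many probes share could lower the count in most splits and raise it in a few. The median of the other splits was 434 and 65 of 99 lay below their expected count. The highest, 872, stayed under 2 times the expected count, a chosen cut for a split far above it. On that cut this stays open as a cause of the low count. Values simulated independently for each probe gave 496, but the spread of such counts over repeated simulations was not tested. The sharing of tanks was not tested. Fish alike within a tank would make p-values too small, which on average raises this count rather than lowers it. The real split is even on slides, and so were 21 of the other splits. Their median was 337, from 255 to 695, and 4 of them lay below 285, while the median of the 78 splits not even on slides was 455. With the slide as a block the median of the 21 was 355, and 16 stayed below their expected count. Within slide 1 alone the count went the other way, 561 where 430 are expected.

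There were 2 unnamed probes that set 4 or more fish of 1 treatment group apart from the other fish by at least 2 log2 units. Chance cannot be excluded, since 68 of the 462 splits, the real one included, gave as many as 2 such probes and the highest other split gave 5.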

How the results depend on the processing

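The count of probes changed by haloperidol, in total, higher and lower, was 0 in limma under all 29 alternatives run, including each of the 12 fish left out and an adjusted p under 0.1, and the lowest adjusted p of a named gene was 0.996. Chosen after seeing the data were keeping flagged spots, a filter on at least 3 arrays (317 of 10866 probes at an unadjusted p under 0.05) and leaving out 2 arrays or 3 fish together. The count at an unadjusted p under 0.05 was 285 and lay between 259 and 381 with 1 fish left out; it was 144 with median centring, where the cause was not tested, and 789 without a brightness filter, where 21363 probes were tested. The count at an unadjusted p under 0.001 ranged from 1 to 10. Aquantile left the log ratios as they were, so it tested nothing. No gene list could be tested, so alternatives for lists were not run, except that without a brightness filter the 5 names of the gonadotropin, steroid and growth factor list gave camera p = 0.50, 0.57 with an estimated correlation and 0.61 with fry, on signals mostly not above background. No paired analysis was possible because the labels do not tie fish of the groups to each other. Of 248 values of the 9 named genes under the alternatives, 0 passed the threshold. Of these, 58 equalled the value given above before it was rounded for printing, and so tested no direction. Among them were all values under the changed brightness filters, trend and robust settings, the slide as a block and Aquantile. Of the other 190, 168 kept their direction and 22 turned it. Lamin B1, complement C3S, adenosine deaminase and cyclin B1 kept their direction throughout; with the filter on all 12 arrays, lamin B1, complement C3S, alpha amylase and ACTRIIB had no value.

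Zona pellucida glycoprotein 3 (-0.02) turned to 0.0804 with Agilent's processed signals, 0.0410 with median centring, 0.0809 with the series matrix values and 0.044 without the 3 fish with high alpha amylase, and lay between -0.12 and 0.13 with 1 fish left out. ACTRIIB turned to 0.0015 without background subtraction and 0.0062 with Cy5 alone, and lay between -0.13 and 0.0017 with 1 fish left out. Without the 3 fish, which by construction removes the high values, alpha amylase was at 0.13, and it lay between -1.95 and 0.057 with 1 fish left out. Without the 2 arrays with the least alike duplicate spots, cytochrome b was at -0.30, pentraxin at -0.0105 and complement C3S at 0.20. With 1 fish left out, cytochrome b lay between -0.013 and 0.40 and pentraxin between -0.059 and 0.13. For the turned values of zona pellucida glycoprotein 3, ACTRIIB and pentraxin, each within its standard error of 0, the cause was not tested. Signal over background limits what could be tested: 19 of the 33 named probes were not well above background in any ovary. Of the tested genes, lamin B1, complement C3S, alpha amylase and ACTRIIB were not so on all 12 arrays.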

Other observations

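All values in this part were sought after seeing the data.

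Single probes parted the fish into a high and a low set. Among 9426 probes that were well above background in Cy3 or in Cy5 on all 12 arrays and had a value on each, 61 had a gap of at least 2 log2 units between neighbouring fish with at least 2 fish on each side. They made 47 different partitions, 41 of them seen in 1 probe. The most common partition, 7 probes including alpha amylase, set control 5, control 6 and haloperidol 5 above the other 9 fish. The median log2 ratio of these 7 probes was 2.66 in control 6, 0.18 in haloperidol 5 and -0.77 in control 5, and lay between -4.40 and -3.81 in the others. Another 5 probes set control 5, haloperidol 2 and haloperidol 5 above the other 9 fish. The other probes of both sets have no gene name in the files.

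Of the 61 probes, 1 parted 5 of the 6 haloperidol fish from all other fish. This unnamed probe, EA_Pp_70750, was chosen after its values were seen. Its log2 ratio was 0.87 to 1.82 in haloperidol 2 to 6, -2.46 in haloperidol 1 and -3.31 to -2.43 in the controls. It was well above background in Cy5 on 5 arrays, in 5 haloperidol and 0 control fish, so the filter on 6 arrays kept it out of the 9848 tested probes. No size of change is given, since no control value was well above background. On those values limma without a brightness filter gave a p of 3.1e-05 unadjusted and 0.66 adjusted over 21363 probes. The adjusted p was 0.53 with a filter on 3 arrays and 0.23 with the slide as a block. Another unnamed probe, also chosen after its values were seen, was at 1.44 to 2.26 in control 1, 2, 4 and 5 and at -2.03 to -1.06 in the other 8 fish. It was well above background in 4 control and 0 haloperidol fish, and its limma adjusted p without a filter was 0.99997. As many as 2 such probes occurred in 68 of 462 splits of the fish.

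Over 5068 probes that were well above background in Cy5 on all 12 arrays and had a value on each, 2 arrays of the same group correlated across probes at a median of 0.20 and 2 arrays of different groups at 0.23, with probes not independent of each other. Arrays of the same slide correlated at a median of 0.24 and those of different slides at 0.20. Pairs ranged from -0.07 to 0.55. Control 4 and haloperidol 4 correlated at 0.55, control 5 and haloperidol 4 at 0.48, and control 4 and control 5 at 0.40. Control 6 and haloperidol 5, both high in alpha amylase, correlated at 0.35 with each other. With haloperidol 1 they correlated at 0.23 and 0.26, and with the remaining fish between -0.07 and 0.14. Control 5, also high in alpha amylase, correlated at -0.03 with each of them.

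The reference pool was compared with the ovaries on the same arrays. Of the 9426 bright probes, 0 were at least 2-fold brighter in Cy3 on all 12 arrays and 0 were at least 2-fold brighter in Cy5. Across them the Cy5 signal of a fish correlated at a median of 0.970 with the Cy3 of its own array, 0.965 with the Cy3 of other arrays and 0.943 with the Cy5 of other fish. The mean log2 ratio of these probes over the arrays ran from -0.72 at the 1st percentile to 0.35 at the 99th. Transcripts scarce in ovary but plentiful in liver or brain would be brighter in Cy3. For the bright probes, the values thus argue against a large share of either tissue in the pool. Its exact make-up, gonad, liver and brain per the labels, could not be checked with gene names on only 33 probes. In Cy3, 12141 probes were well above background on all 12 arrays, against 7752 in Cy5, and 257 were so in Cy3 on all arrays and in Cy5 on none.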
